A study of Mus musculus with 6 samples.

How the data were processed

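Gene expression was measured in B16F10 mouse melanoma cells after 48 h in medium alone or with 2.5 µM or 40 µM of the compound called SQ-diEG or di-sq in the labels. Samples were grouped by their titles and treatment labels into control, 2.5 µM and 40 µM, with 2 arrays each and replicate numbers from the titles. Some description fields do not match these labels (a 2.5 µM sample described as medium, and 3 samples whose description names another treatment). The titles, source names and treatment fields were followed.

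Per the labels' protocols, total RNA was made into biotin-labelled cRNA and hybridised to single-colour Affymetrix mouse arrays. The protocols speak of 3' expression array strips, while the names of the deposited features are transcript clusters, as on another Affymetrix array type, and the amount of input RNA differs between the series' design text and the labels. The deposited table holds log2 values that the authors made with RMA, per the submitters' processing notes, which name Affymetrix Expression Console, RMA and Transcriptome Analysis Console without versions or settings. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a feature, so that differences in total signal between arrays are removed. The deposited log2 values reached 19.9, and between 259 and 269 features per array lay above 16, the log2 maximum of a 16-bit scanner image. The scale therefore departs from the plain log2 scanner scale through a step not given in the sources used here. Whether that step changes the folds is not known, and folds are on the deposited log2 scale. Filters, batch treatment and the genome build are not given in the sources used here, and no coordinates were used.

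The table had 28846 features, of which 6640 were controls and 22206 transcript clusters. The platform annotation used here gave 19572 clusters exactly 1 gene symbol, none several, and 2634 no symbol. These were left out. A gene with several clusters, as 55 genes had, was represented by the cluster with the highest mean over the 6 arrays, which left 19505 genes, with no filter on level. No detection calls were used. As a measure of background, the 95th percentile of the negative control features was taken on each array, between 9.80 and 10.06, with a mean of 9.94. Between 3939 and 4566 genes lay above it. Arrays give no read depth, and the number of arrays limits the precision. No column of another series was present.

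Each comparison (40 µM with control, 2.5 µM with control, 40 µM with 2.5 µM) was tested with limma 3.58.1 in R 4.3.3, on all 6 arrays, with group means, no covariates, and a variance prior that followed the mean level. The fit had 3 residual degrees of freedom and a prior worth 4.11. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Nothing in the labels says that replicates are separate cultures or that equal numbers mark a shared batch.

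Gene lists were tested with camera, at a preset correlation of 0.01 between genes, with adjustment over the 35 lists of a comparison. Of 613 genes on the lists 556 were measured, 14 of them matched through an older symbol. The lists covered cholesterol synthesis and SREBP2, LXR targets and sterol efflux, fatty acid synthesis, fatty acid oxidation and PPAR, melanogenesis (called pigment cell genes), lysosome and autophagy, the unfolded protein response and ATF4, NRF2 and oxidative stress, heat shock, p53 targets, apoptosis regulators, mitosis, DNA replication, cyclins of G1 and their inhibitors, MYC and ribosome biogenesis, ribosomal proteins, the interferon response, class I antigen presentation, NF-kB and inflammation, hypoxia, glycolysis, oxidative phosphorylation, mesenchymal and invasion genes, extracellular matrix, immediate early and MAPK feedback genes, WNT and TGF-beta signalling, xenobiotic metabolism, metallothioneins and iron, replication histones, housekeeping genes, neural crest genes, and markers of fibroblasts, keratinocytes, leukocytes and endothelium. Some genes are on more than 1 list, such as Me1, Scd1, Hmox1, Slc7a11 and Slc2a1. Lists were also tested with a correlation estimated from the arrays and with fry, which tests whether a list's genes move on balance in a shared direction. No list passed with either, in any of the 3 comparisons. The mixed form of fry, which takes changes in either direction together and was not fixed beforehand, did pass for some lists. For 40 µM against control these were LXR targets (adjusted p = 0.0214), mesenchymal and invasion genes, extracellular matrix (0.0118 each) and fibroblast markers (0.0214). For 2.5 µM against control it was extracellular matrix (0.00266). For 40 µM against 2.5 µM these were NRF2, mesenchymal and invasion genes, extracellular matrix (0.0146 each), LXR targets, melanogenesis (0.0101 each) and immediate early genes (0.0389). The counts adjusted over the list alone use the limma p-values of the members.

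Design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison and direction, the 10 largest changes among genes that passed. As none passed, it takes the 5 genes with the smallest unadjusted p whose arrays did not overlap between the groups and whose higher mean was at or above the median of all features (5.94), leaving out predicted genes with no standard symbol. It adds up to 4 members with the smallest p of each list that passed or had members that passed, and Tyr, Tyrp1, Dct, Mitf, Sqle, Abca1, Cdkn1a, Ddit3 and Hmox1 in any case. Some further genes fixed for naming in any case have no feature in the platform annotation used here and were not analysed.

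The scripts were tested on simulated data with the group sizes of these arrays, gene variances modelled on them and 19505 genes. In the measured data the median standard deviation of a gene was 0.0875 in control, 0.192 at 2.5 µM and 0.259 at 40 µM. Whether the recovery rates hold under such unequal spread was not tested, so they are not estimates of the power on these arrays. For 40 µM against control, limma recovered 4.48% of genes changed 2-fold, 78.1% of those changed 4-fold and 94.4% of those changed 8-fold. For 2.5 µM against control these were 5.47%, 73.1% and 93.9%, and for 40 µM against 2.5 µM 4.48%, 74.1% and 93.4%. In 20 simulated data sets for 40 µM against control, camera recovered a list shifted by 0.5 on the log2 scale each time and made 1 false call over 35 lists, with genes drawn independently. The effect of shared controls was taken from 100 simulated data sets without effects, with the same spread of a gene in all groups.

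Alternatives were quantile normalization, centring on the median, a filter on dim genes, the mean of a gene's clusters, a variance prior without a trend, a robust prior (for genes), fitting only the compared groups, the replicate number as a block, leaving out each array, other thresholds, the estimated correlation and fry. Chosen after seeing the data were a block for the arrays low in hybridisation controls (2.5 µM replicate 1 and 40 µM replicate 1), their omission, array weights, and 1 control array to each dose for the correlation of fold changes. The weights came out equal for both arrays of a group (3.25 in control, 0.777 at 2.5 µM and 0.396 at 40 µM), so they weigh groups and not single arrays.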

Results

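The series measured gene expression in B16F10 cells, a pigmented mouse melanoma line, with single-colour Affymetrix oligonucleotide arrays. The cells had been kept for 48 h in medium alone (control) or in medium with the compound that the labels call SQ-diEG or di-sq, at 2.5 µM or at 40 µM. Each of the 3 groups held 2 arrays, and the deposited values are log2 expression values from robust multi-array averaging (RMA). The median over all measured features lay between 5.92 and 5.98 on the 6 arrays. The labels do not say that the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. With 2 arrays per group, the number of arrays limits the precision.

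The 2 control arrays were closer to each other (r = 0.998 across genes) than the 2 arrays at 40 µM (r = 0.983), and the median standard deviation of a gene was 0.0875 in the controls, 0.192 at 2.5 µM and 0.259 at 40 µM on the log2 scale. Replicate 1 at 2.5 µM and replicate 1 at 40 µM stood apart from the other 4 arrays. Their hybridisation controls averaged 10.4 and 10.3 against 10.8 to 11.2 on the others, their poly-A controls averaged 5.65 and 5.63 against 6.35 to 7.42, and the interquartile range of their genes was 5.20 and 5.44 against 4.90 to 4.94. These 2 are called the low arrays. Among the other 4, 40 µM replicate 2 had the highest controls, at 11.154 and 7.42, against 10.8 to 10.9 and 6.35 to 6.79.

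The comparison of 40 µM with control asked which genes the higher dose changed after 48 h. Genes of the oxidative stress list, most of them targets of the transcription factor NRF2, rose together, with 19 of 21 measured members higher and a median log2 change of 0.68 (camera, adjusted p = 5.8e-08; adjusted p = 0.657 with an estimated correlation). Srxn1, which encodes sulfiredoxin, had a mean log2 expression of 11.81 ± 0.06 at 40 µM and 10.32 ± 0.16 in control (SD, n = 2), a log2 change of 1.49 with a standard error of 0.19. Pgd of the pentose phosphate pathway differed by 1.36 with a standard error of 0.24, Gsr (glutathione reductase) by 1.01 with 0.22 and Txnrd1 (thioredoxin reductase) by 0.80 with 0.15, all higher at 40 µM. Adjusted over the list alone, 6 members passed, these 4 together with Osgin1 and Gclm, and adjusted over all genes tested none did, the smallest adjusted p of a member being 0.334 (limma). The list's median against the control mean was 1.05 on 40 µM replicate 1 and 0.42 on replicate 2. Hmox1 (heme oxygenase 1), an often used NRF2 target, lay at 17.54 ± 0.75 at 40 µM and 17.30 ± 0.04 in control (SD, n = 2), a difference within its error (log2 change 0.24, limma adjusted p = 0.764). On 40 µM replicate 1 it was below both controls, at 17.02, and on replicate 2 above them, at 18.07.

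**Figure D1:**
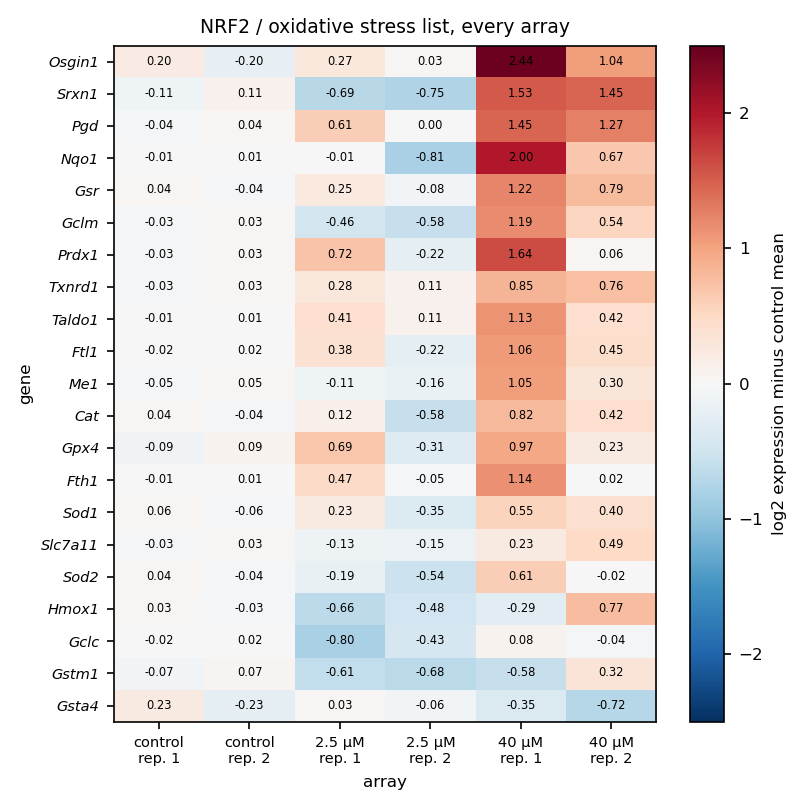
Log2 expression of the 21 measured genes of the NRF2 list on each of the 6 arrays, as the difference from the mean of the 2 control arrays (colour scale in log2 units). Most genes lie above control on both 40 µM arrays, with a median of 1.05 on replicate 1 and 0.42 on replicate 2, while the 2.5 µM arrays have medians of 0.12 and -0.22.

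Both sterol lists, of synthesis and of efflux, passed as higher at 40 µM. In the cholesterol synthesis list, whose genes answer to the sterol-regulated factor SREBP2, 17 of 19 members were higher with a median log2 change of 0.44 (camera, adjusted p = 7.61e-04; adjusted p = 0.657 with an estimated correlation). Sqle (squalene epoxidase) was 2.30-fold higher. Fdps (farnesyl diphosphate synthase) was higher by 1.28 on the log2 scale with a standard error of 0.37, Idi1 (isopentenyl diphosphate isomerase) by 1.36 with 0.46 and Cyp51 (lanosterol demethylase) by 0.44 with 0.17. Adjusted over the list alone, Sqle passed (limma, adjusted p = 0.016) and the other 18 did not, and none passed over all genes. On replicates 1 and 2 at 2.5 µM the list's median against control was 0.39 and 0.17. The list's median was 0.78 on 40 µM replicate 1 and 0.17 on replicate 2, and the call was lost without replicate 1 (camera, adjusted p = 0.135). In the list of targets of the liver X receptors (LXR) and sterol efflux genes, 10 of 13 members were higher with a median of 0.40 (camera, adjusted p = 0.00316; adjusted p = 0.657 with an estimated correlation). Abca1, the transporter that passes cholesterol to lipid-poor apolipoproteins, had a mean of 9.58 ± 0.08 at 40 µM and 8.02 ± 0.13 in control (SD, n = 2), 2.96-fold higher. Lpcat3, a phospholipid acyltransferase, was 1.98-fold higher and Mylip, a ubiquitin ligase, 1.88-fold higher. Adjusted over the list alone, these 3 passed, and none passed over all genes. Scd1 of the same list differed by 0.52 with a standard error of 0.23 and did not pass. The list's median was 0.48 on 40 µM replicate 1 and 0.16 on replicate 2, and 0.27 and -0.04 on replicates 1 and 2 at 2.5 µM. The means of Abca1, Fdps and Idi1 lay in all 3 groups below 9.94, the 95th percentile of the negative control features averaged over the arrays, and that of Sqle did in control and at 2.5 µM.

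The list of the unfolded protein response and its factor ATF4 passed as higher too, with 16 of 21 members higher and a median log2 change of 0.37 (camera, adjusted p = 0.0161; adjusted p = 0.657 with an estimated correlation). Its members with the smallest p were chaperones and cochaperones of the endoplasmic reticulum. Hsp90b1 (GRP94) was higher by 1.30 with a standard error of 0.32, Hspa5 (BiP) by 0.52 with 0.13, Dnajb9 by 0.90 with 0.27 and Sdf2l1, whose means lay below 9.94 in all 3 groups, by 1.10 with 0.40. None of the 21 passed adjusted over the list alone or over all genes (limma). Ddit3 (CHOP), the stress factor at the proapoptotic end of this response, differed by 0.08 with a standard error of 0.18. Pdia3, an endoplasmic reticulum disulfide isomerase outside the list, was 2.30-fold higher, at 16.30 ± 0.21 against 15.10 ± 0.03 (SD, n = 2). The list's median was 0.25 on 40 µM replicate 1 and 0.19 on replicate 2, and 0.255 and -0.007 on replicates 1 and 2 at 2.5 µM. As a list median, the rise on 40 µM replicate 1 was thus no larger than on the other low array. Gene by gene, the median difference between these 2 arrays was 0.27, with 12 of 21 members higher at 40 µM. Within the replicate 2 pair it was 0.135, with 14 of 21 higher. Its call was lost after quantile normalization (camera, adjusted p = 0.116), with genes at or above the median level only (adjusted p = 0.113) and with the array split as a block (adjusted p = 0.0543).

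The oxidative phosphorylation list, subunits of the respiratory chain and ATP synthase, passed with 20 of 23 members higher and a median of 0.62 (camera, adjusted p = 0.00117; adjusted p = 0.738 with an estimated correlation). Most of this rise lay on a single array. The median against control was 1.30 on 40 µM replicate 1 and -0.01 on replicate 2, and 0.75 and -0.02 on replicates 1 and 2 at 2.5 µM, so it followed the arrays low in hybridisation controls at both doses. Atp5o, for example, was at 12.88 and 10.88 on the 2 arrays at 40 µM and at 10.53 and 10.65 in control, and Atp5a1, Sdhc and Uqcrc2 had log2 changes of 0.90, 0.54 and 0.82 with standard errors of 0.39, 0.24 and 0.40. The means of Uqcrc2 lay below 9.94 in all 3 groups. None of the 23 passed adjusted over the list alone or over all genes (limma). The call was lost with genes at or above the median level only (camera, adjusted p = 0.05735), without 40 µM replicate 1 (adjusted p = 0.908), with the array split as a block (adjusted p = 0.519) and without both low arrays (adjusted p = 0.964). In the last case the direction turned to lower.

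The pigment cell list did not pass at 40 µM. Tyr, Tyrp1 and Dct, the enzymes of melanin synthesis, had log2 changes of -0.17, 0.10 and -0.05, with 95% confidence intervals from -0.61 to 0.26, from -0.27 to 0.47 and from -0.36 to 0.25. Tyrp1 and Dct lay at 18.95 and 18.97 in control, near the top of the scale (maxima of 19.71 to 19.88), and saturation of their features was not tested. Mitf, the lineage transcription factor that drives them, had a mean of 15.31 ± 0.29 at 40 µM and 15.99 ± 0.06 in control (SD, n = 2), a log2 change of -0.68 with a standard error of 0.18 that did not pass over all genes (limma, adjusted p = 0.349). Mlph (melanophilin, a melanosome transport adaptor) and Kit (the stem cell factor receptor) were lower, with log2 changes of -0.87 and -0.92, and Rab38, a melanosome trafficking GTPase, was higher by 0.58. Adjusted over the list alone, Mlph passed (limma, adjusted p = 0.0339) and the other 25 members did not, and the list as a whole had a median of -0.04 (camera, adjusted p = 0.594).

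Members of several further lists passed adjusted over the list alone, although none passed over all genes and none of these lists passed as a whole. In fatty acid oxidation and its regulators (median 0.04, camera adjusted p = 0.474), Slc25a20, the mitochondrial carnitine-acylcarnitine carrier, and Cd36 were higher by 1.31 and 0.69, Ppargc1a, a coactivator of mitochondrial biogenesis, had a log2 change of -0.83, and Pdk4 with -0.57 did not pass. In glycolysis (median 0.13, adjusted p = 0.184), the glucose transporter Slc2a1 was higher by 0.73 and Pfkfb3 had a change of -0.97, while Pfkp and Aldoc, with 0.77 and 0.69, did not pass. Slc2a1 alone passed in the hypoxia list (median 0.17, adjusted p = 0.272), where Vegfa, Egln3 and Ndrg1 had changes of -0.59, 0.61 and 0.37. In the metal and iron list (median 0.16, adjusted p = 0.272), the iron exporter Slc40a1 passed with 1.25. Mt1 and Mt2, the metallothioneins, had larger changes of 1.92 and 1.98 with standard errors of 0.70 and 0.71 and did not pass, Mt1 being at 18.04 and 15.74 on the 2 arrays at 40 µM, and Ftl1 had 0.75. In the mesenchymal and invasion list (median -0.09, adjusted p = 0.272), Mmp2 passed with a lower level, and Fn1, Snai2 and Snai1 did not, with log2 changes of -0.96, -0.66 and -0.70. In the extracellular matrix list (median -0.11, adjusted p = 0.545), Ccn1 passed with 0.96 and Col5a2 with -0.99, whereas Postn and Col18a1 had -0.66 and -0.49. Slc25a20, Cd36, Pdk4, Mmp2, Snai1, Snai2, Egln3, Col5a2, Postn and Col18a1, and Kit among the pigment cell genes, had means below the 9.94 of the negative control features in all 3 groups. Those of Cd36, Pdk4, Mmp2, Snai1, Col5a2, Postn and Col18a1 lay even below the medians of these features (5.98 to 6.101), so their changes are between background values. Aldoc and Slc40a1 lay below 9.94 in control and at 2.5 µM, and Fn1 did at 40 µM.

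The remaining lists did not pass at 40 µM (camera). The heat shock list had a median log2 change of 0.20 (adjusted p = 0.0651), ribosomal proteins 0.41 (adjusted p = 0.105) and fatty acid synthesis 0.22 (adjusted p = 0.162). Heat shock and ribosomal proteins passed as higher with the replicate block, with array weights and without 40 µM replicate 2. Fatty acid synthesis did without 40 µM replicate 1, with the array split as a block and without both low arrays. Ribosomal proteins passed as lower without both low arrays. Without 40 µM replicate 1 and without both low arrays, DNA replication and the mesenchymal and invasion list passed as lower and replication histones as higher. DNA replication also passed as lower with the array split as a block. The metal and iron list passed as higher without both low arrays. Mitotic and housekeeping genes passed as higher without 40 µM replicate 2. Ribosomal proteins and housekeeping genes (median 0.13, adjusted p = 0.39) moved with the array split, their medians being 0.83 and 0.50 on 40 µM replicate 1 and -0.17 and -0.11 on replicate 2. Proliferation lists gave a median of 0.10 for mitotic genes (adjusted p = 0.337), -0.16 for DNA replication (adjusted p = 0.471), -0.06 for cyclins of G1 and their inhibitors (adjusted p = 0.545), 0.02 for MYC and ribosome biogenesis (adjusted p = 0.621) and -0.23 for replication histones (adjusted p = 0.917), the histones being at -0.77 on replicate 1 and 0.22 on replicate 2. Targets of p53 had a median of -0.07 (adjusted p = 0.783) and apoptosis regulators 0.05 (adjusted p = 0.733), and Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, had a log2 change of 0.04 with a standard error of 0.22. Signalling and immune lists had medians of 0.07 for NF-kB and inflammation (adjusted p = 0.331), 0.15 for the interferon response (adjusted p = 0.474), -0.15 for class I antigen presentation (adjusted p = 0.693), 0.03 for immediate early and MAPK feedback genes (adjusted p = 0.621) and 0.07 for WNT and TGF-beta signalling (adjusted p = 0.693). Lysosome and autophagy genes had -0.02 (adjusted p = 0.594), xenobiotic genes -0.01 (adjusted p = 0.993) and neural crest genes -0.16 (adjusted p = 0.183). Markers of cells other than melanoma cells were lower or close to control, with medians of -0.08 for fibroblasts (adjusted p = 0.321), -0.23 for keratinocytes (adjusted p = 0.64), -0.25 for leukocytes (adjusted p = 0.321) and -0.20 for endothelium (adjusted p = 0.294). All of these markers lay below 9.94, and most below the medians of the negative control features (5.98 to 6.101), so these are differences between background values. The median differed in sign from the mean or the test in 3 lists, those of the lysosome, replication histones and xenobiotic genes.

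No gene passed over all 19505 genes tested at 40 µM (limma, smallest adjusted p = 0.334). At an unadjusted p under 0.05, 1011 genes were higher and 1338 lower, where chance alone gives 975 in all, and 206 of the higher and 186 of the lower genes also differed at least 2-fold. Besides those named above, the genes with the smallest p were Zfp189 and Fryl, higher by 1.62 and 1.40, and Nr1i3, Coq8a, Cpne4, Prickle1 and Masp1, with log2 changes of -1.64, -1.32, -1.29, -1.04 and -1.27 (adjusted p = 0.334 for each). Coq8a is a kinase-like protein of coenzyme Q synthesis. Zfp189, Nr1i3 and Cpne4 had means below 9.94 in all 3 groups, Fryl in control and Coq8a at 40 µM. Nr1i3 lay at 6.45 in control and 4.81 at 40 µM, while the medians of the negative control features were 5.98 to 6.101, so its fold is between values not clearly above background. Of the genes with a 2-fold difference, 168 of the 206 higher and 176 of the 186 lower lay below 9.94, where 78.7% of all genes lay. The count depended on the arrays kept. Without 40 µM replicate 2, 2235 genes passed, 1456 higher and 779 lower, with 1 array left at 40 µM that is assumed to vary like the other groups. Without both low arrays 3749 passed, with an error estimated from the 2 controls alone.

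**Figure D2:**
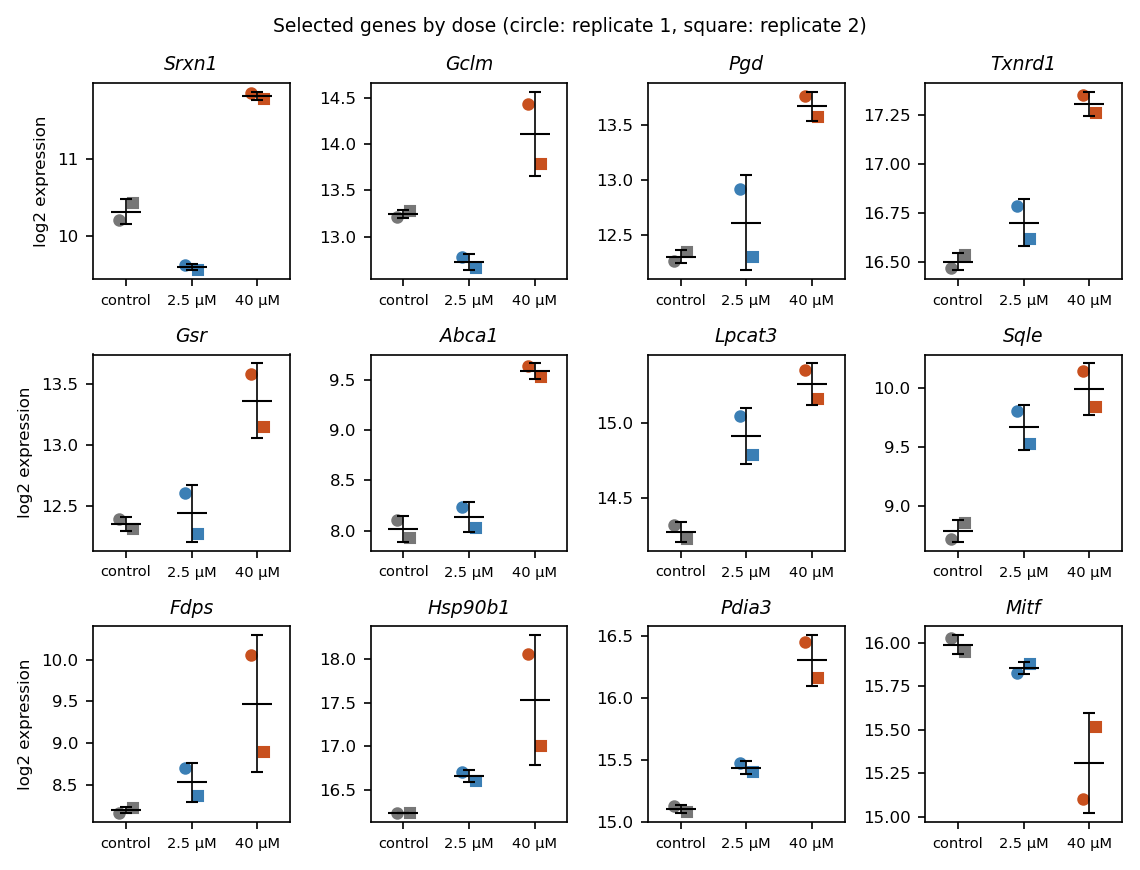
Log2 expression of 12 genes against dose, with circles for replicate 1, squares for replicate 2 and black bars for the mean ± SD (n = 2 arrays per group). Srxn1 and Abca1 lie above control on both 40 µM arrays, at means of 11.81 and 9.58 against 10.32 and 8.02, while Mitf lies below, at 15.31 against 15.99.

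The comparison of 2.5 µM with control asked the same of the lower dose. No list passed (camera) and no gene passed (limma, smallest adjusted p = 0.479). Sqle was 1.84-fold higher, with a log2 change of 0.88 and a standard error of 0.22, within a cholesterol synthesis list of which 14 of 19 members were higher (median 0.30, camera adjusted p = 0.529). Srxn1 lay at 9.60 ± 0.04 and Gclm at 12.72 ± 0.09 against 10.32 ± 0.16 and 13.24 ± 0.04 in control (SD, n = 2), below control at this dose. This level of Srxn1 is under 9.94, the 95th percentile of the negative control features, so the size of its difference is not certain. The NRF2 list had 12 of 21 members lower and a median of -0.06 (camera, adjusted p = 0.529). The NRF2 list passed as lower at 2.5 µM with the array split as a block and without both low arrays, alternatives chosen after seeing the data. Abca1 differed by 0.12 with a standard error of 0.21, and Mitf, Tyr, Tyrp1 and Dct by -0.14, 0.02, 0.09 and 0.07.

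The list closest to passing at 2.5 µM was oxidative phosphorylation, with 22 of 23 members higher and a median of 0.38 (camera, adjusted p = 0.0693; adjusted p = 0.951 with an estimated correlation), which came from replicate 1. It passed as higher when only the compared groups were fitted, with the replicate block, with array weights, and without control replicate 2, 2.5 µM replicate 2 or either 40 µM array. It was followed by NF-kB and inflammation with 14 of 19 members higher (median 0.13, adjusted p = 0.175) and by the mesenchymal and invasion list with 17 of 23 lower (median -0.12, adjusted p = 0.175). The mesenchymal and invasion list passed as lower with the array split as a block. The other 32 lists had adjusted p-values from 0.529 to 0.97. Among them, ribosomal proteins passed as higher without 2.5 µM replicate 2 and as lower with the array split as a block and without both low arrays. No member of any list passed adjusted over the list alone. The LXR list (median 0.12) and the unfolded protein response list (median 0.12) had an adjusted p of 0.529 each, and Cdkn1a, Ddit3 and Hmox1 differed by 0.03, -0.14 and -0.57, the last with a standard error of 0.32.

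At an unadjusted p under 0.05, 827 genes were higher and 1050 lower at 2.5 µM, where chance gives 975 in all, and 58 and 150 of these differed at least 2-fold. Those with the smallest p were Itgb7 (the integrin beta 7 subunit), Fryl, Adal, Lhfpl2 and Zfp867, higher by 1.41, 1.42, 1.16, 0.99 and 1.04, and Rab7b, Tex29, Prmt3 (a protein arginine methyltransferase), Rpn2 (a subunit of the oligosaccharyltransferase) and Sft2d3, with log2 changes of -1.59, -1.69, -1.12, -0.89 and -1.33 (limma, adjusted p = 0.479 for each). Adal, Zfp867, Rab7b, Tex29 and Sft2d3 had means below 9.94 in all 3 groups, Fryl and Itgb7 in control. Fryl stood at nearly the same level at both doses, 10.70 ± 0.29 at 2.5 µM and 10.69 ± 0.24 at 40 µM against 9.29 ± 0.16 in control (SD, n = 2), and Lhfpl2 did too, at 11.50 ± 0.02 and 11.49 ± 0.03 against 10.51 ± 0.02. Of the genes with a 2-fold difference, 54 of the 58 higher and 144 of the 150 lower lay below 9.94. Without both arrays low in hybridisation controls 3991 genes passed, with an error estimated from the 2 controls alone.

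The comparison of 40 µM with 2.5 µM asked whether the doses differed, and its clearest group was again the NRF2 list. Of its 21 members 20 were higher at 40 µM, with a median log2 difference of 0.66 (camera, adjusted p = 2.07e-16; adjusted p = 0.865 with an estimated correlation). Srxn1 differed by 2.21 with a standard error of 0.19, with the smallest p of all genes (limma, adjusted p = 0.132). At 2.5 µM it lay under 9.94, which limits how far this size can be trusted. Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, differed by 1.38 with a standard error of 0.24, Pgd by 1.05 with 0.24 and Gsr by 0.92 with 0.22. Adjusted over the list alone 11 members passed, and over all genes none did. The median difference between the doses was 0.71 within the pair of replicate 1 arrays and 0.67 within the pair of replicate 2 arrays, with 20 of 21 genes higher at 40 µM in each.

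The lists of cholesterol and fatty acid synthesis passed as higher at 40 µM than at 2.5 µM and that of DNA replication as lower, each lost under several alternatives. In the cholesterol synthesis list 16 of 19 members were higher, with a median of 0.25 (camera, adjusted p = 0.00549; adjusted p = 0.865 with an estimated correlation). Fdps, Mvd, Dhcr7 and Idi1 differed by 0.94, 0.58, 0.40 and 0.84 with standard errors of 0.37, 0.27, 0.19 and 0.46, while Sqle differed by 0.32 with 0.22. The means of Mvd lay below 9.94 in all 3 groups. In fatty acid synthesis 11 of 13 members were higher, with a median of 0.23 (camera, adjusted p = 0.0341; adjusted p = 0.865 with an estimated correlation). Scd1 (stearoyl-CoA desaturase), Me1 (malic enzyme), Fasn (fatty acid synthase) and Elovl1 (a fatty acid elongase) differed by 0.77, 0.81, 0.57 and 0.36 with standard errors of 0.23, 0.26, 0.24 and 0.20. In DNA replication 21 of 27 members were lower, with a median of -0.16 (camera, adjusted p = 0.0399; adjusted p = 0.865 with an estimated correlation), among them Mcm5 of the replicative helicase with -0.58, Uhrf1 with -0.52, Rrm1 of ribonucleotide reductase with -0.51 and the chromatin assembly factor subunit Chaf1b, whose mean at 40 µM lay below 9.94, with -0.59. No member of these 3 lists passed adjusted over the list alone or over all genes (limma). Within the replicate 1 pair the medians were 0.49, 0.09 and -0.07 for cholesterol synthesis, fatty acid synthesis and DNA replication, and within the replicate 2 pair 0.14, 0.30 and -0.38. The cholesterol call was lost without 2.5 µM replicate 2 (adjusted p = 0.169), without 40 µM replicate 1 (adjusted p = 0.777) and without both low arrays (adjusted p = 0.399). The fatty acid call was lost after quantile normalization (adjusted p = 0.0553), without a trend in the variance prior (adjusted p = 0.0503), and without 2.5 µM replicate 1, 2.5 µM replicate 2 or 40 µM replicate 2 (adjusted p = 0.142, 0.119 and 0.252), and the DNA replication call after centring on the median (adjusted p = 0.0593), without that trend (adjusted p = 0.0636), with only the compared groups fitted (adjusted p = 0.0711), and without either control, 2.5 µM replicate 1 or 40 µM replicate 2 (adjusted p = 0.069, 0.069, 0.68 and 0.867).

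Some members of the pigment cell, LXR, metal and iron, and extracellular matrix lists passed adjusted over the list alone between the doses. None of these lists passed as a whole in the main test. Mlph, Kit and Trpm1, a melanocyte cation channel, were lower at 40 µM, with log2 differences of -0.73, -1.06 and -0.81, and passed adjusted over the list alone (limma, adjusted p = 0.0477 for each). The melanosome GTPase Rab27a differed by -0.59 and Mitf by -0.54 and did not pass, and Tyr, Tyrp1 and Dct differed by -0.20, 0.01 and -0.12. The pigment list as a whole, with 16 of 26 members lower and a median of -0.12, did not pass (camera, adjusted p = 0.0819). It passed as lower with genes at or above the median level only (adjusted p = 0.02545), with the replicate block (adjusted p = 0.04945) and without 40 µM replicate 1 (adjusted p = 0.02353). It also did with the array split as a block (adjusted p = 0.03639), without both low arrays and with array weights (adjusted p = 0.03203). These weights were equal for both arrays of a group and do not single out the low arrays. In the LXR list (median 0.14, adjusted p = 0.0813), Abca1 was 2.73-fold higher at 40 µM and alone passed adjusted over the list, whereas Mylip, Scd1 and Lpcat3 had differences of 0.89, 0.77 and 0.34. The LXR list passed as higher with genes at or above the median level only, with the replicate block, with the array split as a block, with array weights, without both low arrays, without 2.5 µM replicate 1 and without 40 µM replicate 2. In the metal and iron list (median 0.25, adjusted p = 0.179), Slc40a1 passed adjusted over the list alone with 1.06 and Hamp (hepcidin) with -0.91, while Hmox1 and Ftl1, with 0.81 and 0.67, did not. This list passed as higher with the replicate block, with the array split as a block, with array weights and without both low arrays. Ccn1 passed in the extracellular matrix list with 1.16 (median 0.00, adjusted p = 0.834), whose members Col5a2, Postn and Thbs1 had -0.53, -0.43 and -0.48. Hamp, with means of 7.03, 7.92 and 7.01 in control, at 2.5 µM and at 40 µM, and Thbs1 lay below 9.94 in all 3 groups, Thbs1 also below the medians of the negative control features. No member of these 4 lists passed over all genes.

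The lists not named for this comparison had adjusted p-values from 0.13 to 0.866 (camera), the lowest being those of ribosomal proteins, the unfolded protein response and heat shock, with medians of 0.21, 0.13 and 0.28. These 3 passed as higher with the array split as a block, among other alternatives. Oxidative phosphorylation passed as higher with that block and without 2.5 µM replicate 1 or 40 µM replicate 2, but as lower without 40 µM replicate 1. Mitotic genes passed as higher without 40 µM replicate 2 and as lower without 40 µM replicate 1. Replication histones passed as higher without 40 µM replicate 1 and without both low arrays. No gene passed over all genes in the comparison of the doses (limma, smallest adjusted p = 0.132), and with the array split as a block Srxn1 did (adjusted p = 0.0275). At an unadjusted p under 0.05, 456 genes were higher and 639 lower at 40 µM, where chance gives 975 in all, and 41 and 42 of these differed at least 2-fold. Besides Srxn1, Abca1, Ccn1 and Gclm, the genes with the smallest p were Ephx1, the microsomal epoxide hydrolase, higher by 1.15, and Prickle1, St3gal4, Gsdmc, Cwh43 and Coq8a, with log2 differences of -1.34, -1.50, -1.23, -1.33 and -1.11 (adjusted p = 0.854 for each). The means of Cwh43 lay below the medians of the negative control features in all 3 groups, and those of Coq8a and St3gal4 below 9.94 at 40 µM. Cdkn1a and Ddit3 differed by 0.01 and 0.21. Of the genes with a 2-fold difference, 34 of the 41 higher and 36 of the 42 lower lay below 9.94. Without both arrays low in hybridisation controls 2965 genes passed, with an error estimated from the 2 controls alone.

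**Figure D3:**
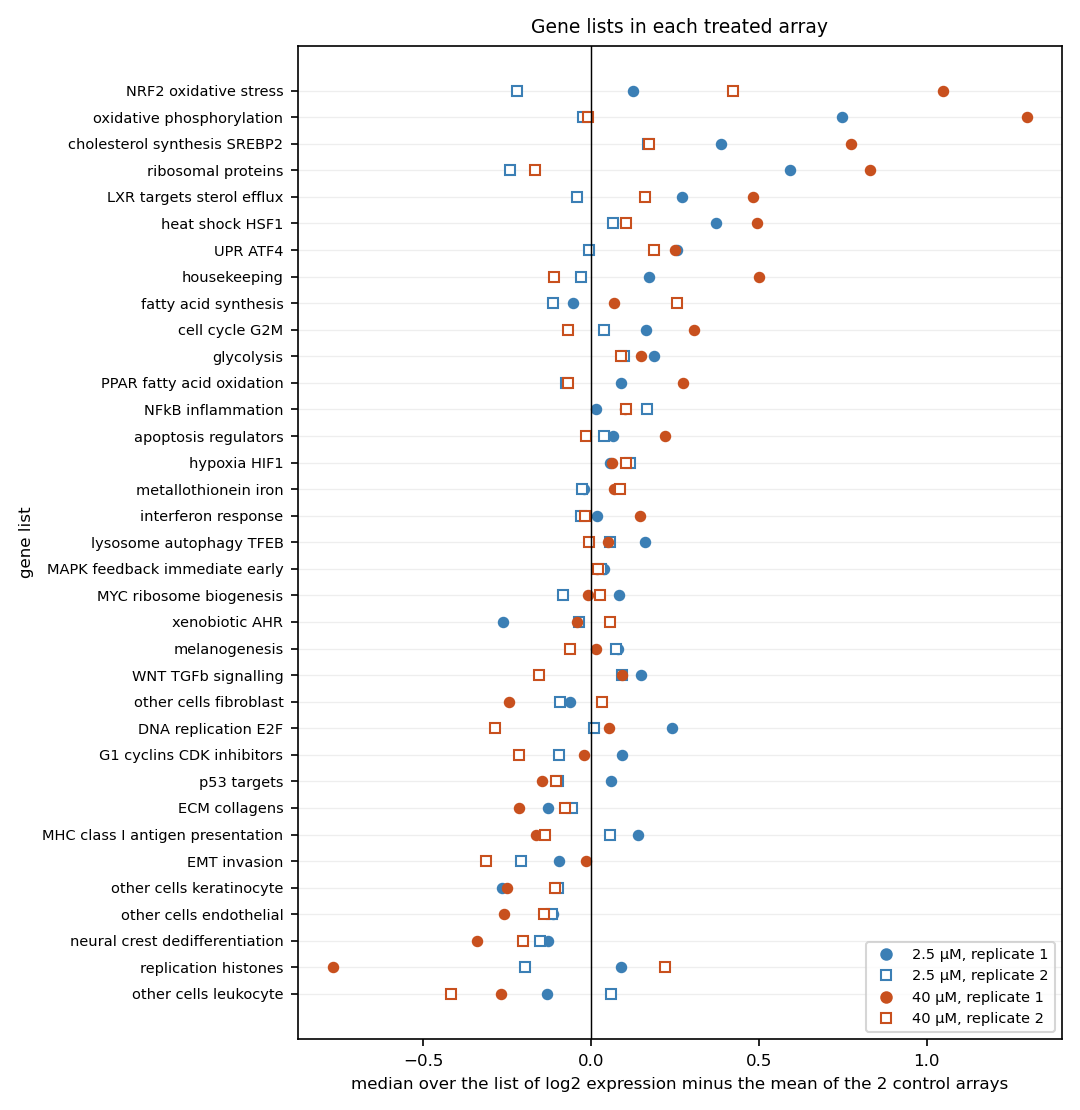
Median log2 difference from the control mean of each of the 35 gene lists on the 4 treated arrays, with 1 mark per list and array. Oxidative phosphorylation lies at 0.75 and 1.30 on the replicate 1 arrays and at -0.02 and -0.01 on the replicate 2 arrays, whereas the NRF2 list lies above 0 on both 40 µM arrays, at 1.05 and 0.42.

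The log2 fold changes at both doses against control were compared across the 19505 genes, which are not independent replicates. They correlated with r = 0.692, and 73.9% of genes had the same sign. Both comparisons used the same 2 controls. In 100 simulated data sets with no effect, controls included, the mean r was 0.501 and 66.7% of genes had the same sign. The simulation gave a gene the same spread in all groups. Measured median standard deviations were 0.0875 in control, 0.192 at 2.5 µM and 0.259 at 40 µM. Tighter controls add less shared variation, so the simulated values may be too high as a baseline for these arrays. The covariance was 0.113 against a simulated 0.0408, a difference of 0.0724 that carries the same limit. With 1 control array to each dose, so that none was shared, r was 0.571 and 0.575 and the covariance 0.101 in both arrangements, a split chosen after seeing the data. The correlation also depended on the 2 low arrays. It was 0.476 without 40 µM replicate 1, 0.477 without 2.5 µM replicate 1 and 0.432 without both. The simulation was not repeated for these smaller groups. Between single arrays, r was 0.697 for the replicate 1 arrays of both doses, 0.432 for the replicate 2 arrays, and 0.393 and 0.373 for the mixed pairs. All of these subtract the same control mean, which alone raises r, and no value without an effect was simulated for single arrays.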

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

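Chosen after the results were seen were the counts and medians on single arrays, the count of NRF2 genes on opposite sides of control, the array split as a block and the omission of both low arrays, and the use of quantile normalization and the estimated correlation to judge an explanation, while the limma and camera tests themselves and these last 2 alternatives were planned. The results here are genes picked by the rule for named genes that lay on opposite sides of control at the 2 doses. For each, both arrays of a dose lay on the same side of both controls. Slc7a11, not picked by that rule, is given in the next paragraph. The value is the log2 difference between 40 µM and 2.5 µM, which limma tested. For all but Dct (adjusted p = 0.915) and Srxn1 (adjusted p = 0.132) its adjusted p was 0.854. Lower at 2.5 µM and higher at 40 µM were Srxn1 with 2.21, Gclm with 1.38, Ccn1 with 1.16, Me1 with 0.81 and Scd1 with 0.77. Higher at 2.5 µM and lower at 40 µM were St3gal4 with -1.50, Prickle1 with -1.34, Cwh43 with -1.33, Gsdmc with -1.23, Trpm1 with -0.81, Chaf1b with -0.59, Mcm5 with -0.58, Rrm1 with -0.51 and Dct with -0.12. Over all genes, 201 (1.03%) were lower and then higher and 330 the reverse.

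Of the 21 genes of the NRF2 list, 4 were among the 201: Gclm, Srxn1, Slc7a11 and Me1 lay below both controls on both 2.5 µM arrays and above both on the 40 µM arrays. A candidate explanation is a response of NRF2 targets that differs in direction between the doses. The list was counted because some of these genes had shown the pattern, so the count cannot show that the pattern is more common in it. The list's lower level at 2.5 µM did not pass in the main test (camera, adjusted p = 0.529) and passed with the array split as a block and without both low arrays, both at the preset correlation, which leaves this open.

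The higher NRF2 list at 40 µM against 2.5 µM was set against 3 technical explanations. The arrays low in hybridisation controls do not by themselves account for it, since within the replicate 2 arrays, which are not low, 20 of 21 genes were higher at 40 µM. With the split as a block the adjusted p was 9.35e-20 (camera). Each dose held 1 low array, so this block could not change the estimated difference between the doses and does not test the explanation. The replicate 2 arrays were not equal in these controls either, at 10.824 for 2.5 µM and 11.154 for 40 µM. In the replicate 1 pair the 40 µM array was the lower one, at 10.296 against 10.434, and the list was higher at 40 µM in both pairs. The unequal range of the arrays does not either, since after quantile normalization the adjusted p was 3.09e-16. Correlation between the list's genes stays open: with a correlation of 0.2996 estimated from 3 residual degrees of freedom, the adjusted p was 0.8649. Chance and a response to the dose therefore cannot be told apart for this list by that test, and a response remains a hypothesis.

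The rise of the oxidative phosphorylation list at 40 µM may come from the arrays low in hybridisation controls. The list's median against control was -0.01 on 40 µM replicate 2, which is not low, while both low arrays, of different doses, were high. A response of similar size in both 40 µM samples was not seen, as the signed change of 20 of 23 genes on replicate 2 was below 50% of that on replicate 1. This count is not one of distance. It includes genes that lay well below control on replicate 2, such as Cox4i1 with 0.345 and -0.351 and Cox7a2 with 0.556 and -0.433. The list was picked because it passed, and the call was lost without replicate 1. A smaller change on replicate 2 is thus favoured by the selection, which leaves a weaker shared response open. An unequal range of the arrays as the whole cause is argued against, since the median on 40 µM replicate 1 was still 1.16 after quantile normalization. What set these 2 arrays apart, in the cells or in the RNA handling, was not tested, and no biological explanation of the split can be drawn from the labels.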

How the results depend on the processing

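The array split as a block, the omission of both low arrays, the array weights and 1 control array to each dose were chosen after seeing the data; the other alternatives were planned. The count of genes that passed stayed at 0 in all 3 comparisons under every setting run except the following. At an unadjusted p under 0.05 with a 2-fold difference, 392, 208 and 83 genes passed for 40 µM against control, 2.5 µM against control and 40 µM against 2.5 µM. Leaving out each array gave 0 to 2235 genes for 40 µM against control (2235 without 40 µM replicate 2) and 0 in the other comparisons. The split as a block gave 1 gene (Srxn1) for 40 µM against 2.5 µM. Without both low arrays, 3749, 3991 and 2965 genes passed, with the only residual degree of freedom then coming from the controls, the closest pair. Of 5, 0 and 4 lists that passed, the estimated correlation and fry left 0. The filter on dim genes left 3 for 40 µM against control and gave 6 for 40 µM against 2.5 µM, the prior without a trend 2 for 40 µM against 2.5 µM, and fitting only the compared groups gave 1 for 2.5 µM against control. Leaving out each array gave 5 to 9, 0 to 2 and 2 to 8 lists. Without 2.5 µM replicate 2, 2 lists passed for 2.5 µM against control and 2 for 40 µM against 2.5 µM. Without 40 µM replicate 1, 7 passed for 40 µM against 2.5 µM; without 40 µM replicate 2, 9 passed for 40 µM against control and 8 for 40 µM against 2.5 µM. Without control replicate 2 or either 40 µM array, 1 passed for 2.5 µM against control. The split as a block gave 3 lists for 2.5 µM against control and 11 for 40 µM against 2.5 µM, array weights 1 and 9, and the omission of both low arrays 10, 2 and 9, with oxidative phosphorylation at 40 µM then turned to lower (adjusted p = 0.964). The replicate numbers do not pair the treated arrays with the controls, where deviations of equally numbered arrays correlated with r = -0.005 and -0.012. Between the doses r was 0.386, so equally numbered treated arrays share some structure, which the main test leaves unmodelled. With the replicate block, 0 genes passed, and 1 list for 2.5 µM against control and 8 for 40 µM against 2.5 µM. The correlation of fold changes ranged from 0.476 to 0.715 when leaving out each array (lowest without either replicate 1), was 0.432 without both low arrays, and 0.571 and 0.575 with 1 control array to each dose. Except where the filter or the estimated correlation acts by construction, the cause of these shifts was not tested.

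Of 2095 values of named genes under alternatives, 1933 kept direction and side of the threshold, 137 newly passed and 25 turned, all of Cdkn1a, Tyr, Tyrp1, Ddit3 and Hmox1. Of the new passes, 1 came with the split as a block and all others without 40 µM replicate 2 or without both low arrays. Both of these settings leave 1 array at 40 µM. After quantile normalization, Cdkn1a was at -0.00368 for 40 µM and -0.0147 for 2.5 µM against control, Tyr at -0.00301 for 2.5 µM and Tyrp1 at -0.00223 between the doses. After centring, Tyrp1 and Cdkn1a were at -0.0247 and -0.0233 between the doses. With the split as a block, Cdkn1a was at -0.157 for 40 µM and -0.168 for 2.5 µM, Ddit3 at -0.0451 for 40 µM and Tyrp1 at -0.00345 for 2.5 µM. Without both low arrays, Tyrp1, Cdkn1a and Ddit3 were at -0.0677, -0.098 and -0.0998 for 40 µM, Cdkn1a at -0.227 for 2.5 µM and Tyrp1 at -0.138 between the doses. Leaving out each array, values at 40 µM against control ranged from -0.0677 to 0.264 for Tyrp1, -0.098 to 0.185 for Cdkn1a, -0.0998 to 0.250 for Ddit3 and -0.288 to 0.768 for Hmox1. At 2.5 µM they ranged from -0.145 to 0.193 for Tyr and -0.227 to 0.292 for Cdkn1a, and between the doses from -0.156 to 0.175 for Tyrp1 and -0.248 to 0.270 for Cdkn1a. The alternative without features ending in _s_at or _x_at removes no feature and was not run, nor was the robust prior for lists, which camera does not take. With 78.7% of genes below the 95th percentile of the negative controls, signal over background limits most single-gene values.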

Other observations

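The test in this part was chosen after the result was seen. The 2 samples at 40 µM differed in several gene groups. Mt1 and Mt2 were at 18.04 and 16.26 on replicate 1 and at 15.74 and 14.32 on replicate 2, against 14.97 and 13.31 on average in control. Hmox1 went the other way, at 17.02 on replicate 1 and 18.07 on replicate 2 against 17.30 in control. DNA replication genes had a median against control of 0.06 on replicate 1 and -0.29 on replicate 2, mesenchymal and invasion genes of -0.01 and -0.31, and replication histones of -0.77 and 0.22. Each is a difference between single arrays with no test.

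Without 40 µM replicate 2, limma called 2235 genes against control, and a candidate explanation is that these changes belong to replicate 1 alone. Of these genes, 16.96% departed from the control mean in the same direction and at least 50% as far on replicate 2 as on replicate 1. The median ratio was 0.170, although 72.4% moved in the same direction. On 2.5 µM replicate 1, the other array low in hybridisation controls, 42.9% departed as far in that direction. The genes were called with replicate 1 as the only 40 µM array, its spread being taken from the other groups, so a smaller departure on replicate 2 is favoured by the selection, and the explanation stays open.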
